A study of Mus musculus with 18 samples.

How the data were processed

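Polyadenylated RNA was sequenced from 18 cultures of C2C12, a mouse myoblast line. The cultures fell into 6 groups of 3, and per the labels each library came from a separate culture. The 3 lines were clonal derivatives carrying a doxycycline-inducible transgene: a codon-altered mouse Dux, human DUX4, or firefly luciferase as the control protein. Dux and DUX4 are double-homeobox transcription factors. Induced cultures received doxycycline at 2 µg/ml for 36 h, and uninduced cultures of the same line received none. Groups and replicate numbers came from the labels. Libraries were pooled for sequencing per the labels' protocols, and which pool and lane held each library is not given in the sources used here, so no sequencing batch could be set against the groups.

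The deposited values were whole-number read counts per gene, with one column per library, not normalized. Per the submitters' processing notes, CASAVA, TopHat2 2.0.12 and Bowtie2 2.2.3 were used with the mouse build mm10. The counting program, the gene annotation and the use of strand are not given in the sources used here. Reads shared by near-identical gene copies, by overlapping genes or by antisense genes can therefore not be assigned with certainty to one gene. The table held 24028 genes, of which 5017 had no count in any library. In 27 genes the symbol had been turned into a calendar date by spreadsheet software, and these symbols were restored from the gene identifiers. A symbol was missing for 5 genes. Of all genes, 22826 (95.0%) matched the GENCODE vM21 annotation of GRCm38 (mm10), which gave the positions, transcript lengths and GC contents. Reads from the transgenes themselves were not analysed here, and a list of 13 mitochondrially encoded genes had no match in the table and was not used here.

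The total count per library ranged from 11010586 to 17179642. Genes were kept by the edgeR filterByExpr rule by group, which left 13602 genes for testing. Library sizes were scaled by TMM factors, and CPM, the counts per library scaled to a common total, used these factors. Values are means ± SD over 3 libraries. Changes were tested with the two-sided quasi-likelihood F test of edgeR 4.0.16 in R 4.3.3 on the deposited counts. One model of the 6 group means was fitted to all 18 libraries, which share one estimate of the spread, and p-values were adjusted by Benjamini-Hochberg over the genes tested. A gene was called changed at an adjusted p under 0.05, and strongly changed when the absolute log2 fold change was also at least 2. The biological coefficient of variation was 6.25%. The standard error of a log2 fold change was its size divided by the square root of the F statistic. P-values measure the spread between cultures, pooled over the 3 lines. That spread was unequal. Chi-square per degree of freedom between replicates reached 38.2 in induced mouse Dux libraries and 2.83 in the human DUX4 and luciferase lines. Pooling can therefore make p-values too small for mouse Dux and too large for the other lines. Each transgene had a single clonal line, so line, clone and transgene cannot be separated. A difference between 2 responses was tested as an interaction contrast in the same model. A higher response means a higher log2 fold change, which can be a smaller fall.

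Low counts were treated by one rule. Against a group with no count in any library, a fold is given as at least N-fold from a floor of 3 counts over the group. With 1 to 3 counts, the ratio is given with its 95% exact (Clopper-Pearson) interval. With at most 3 counts in both groups no fold is given. Intervals and floors cover counting error only, since reads copied by PCR are not independent molecules. Medians of gene lists in the 3 single responses are also given with such genes at their bound, or left out where no fold is given, if that changes the printed median.

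Gene lists were tested with camera in limma 3.58.1, two-sided, with the correlation between genes preset to 0.01. The adjustment covered 20 lists in 4 comparisons. The lists were 2-cell-stage genes, mouse counterparts of human DUX4 targets, double-homeobox and PRD-like homeobox genes, pluripotency genes, germline genes, myogenic regulators and myoblast markers, sarcomere and contractile genes, p53 target genes, integrated stress and unfolded protein response genes, heat shock and chaperone genes, interferon-stimulated genes, S-phase genes, G2 and M-phase genes, nonsense-mediated decay and splicing factor genes, chromatin repressors of the 2-cell-like state, cholesterol synthesis genes, collagen and matrix genes, immediate early genes, adipocyte and osteoblast markers, and markers of other cell types. Some genes are on more than one list. Members that failed the filter on low counts were not tested. This left 10 of 25 matched pluripotency genes, 5 of 31 germline genes and 12 of 21 double-homeobox and PRD-like genes. The filter keeps genes counted well enough in a single group, so members changed are not shares of the whole list. The lists, the comparisons, the tests and the rule for naming genes were fixed before the data were examined. That rule named the 8 largest rises and 8 largest falls per comparison (4 and 4 for luciferase) among called genes with at least 5 CPM in the higher group and no overlap between libraries. Chance alone separates 3 libraries from 3 for 10% of genes. Models without a gene name were passed over. The rule added up to 3 members of each list with the smallest p-values and 14 fixed genes, which gave 191 genes in all. Only some of these are named in the text, and a few are not reported here.

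Alternatives chosen before the data were examined were median-of-ratios size factors, library size alone, no filter on low counts, the replicate number as a block, each library left out in turn, DESeq2 1.42.0, only the groups compared in the fit, a minimum fold of 2, an estimated correlation between genes, and fry in place of camera. Added after the data were seen were both mouse Dux libraries numbered 1 left out, a replicate block within the mouse Dux line, the luciferase response subtracted in the list tests, and limma-voom for differences between responses. To check whether replicate numbers in the labels pair the libraries, deviations from the group means were correlated between the induced and uninduced library of each number. In the mouse Dux line the 3 correlations across genes were 0.432, 0.248 and 0.226, so these libraries were treated as paired in the block within that line. Library 1 stood apart in both groups, and deviations from a group mean depend on each other. The 3 correlations are therefore not separate evidence of pairing. The planned replicate block used the number across all lines. In the other 2 lines libraries of one number share only the number. Chi-square tests of the counts found no pair of libraries alike within sampling noise, so each counted as 1 replicate.

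The procedures were tested on simulated counts drawn from the means of these libraries. For mouse Dux induction, with 13051 genes, the edgeR test recovered 87% of 100 genes changed 1.5-fold and 96% of 100 genes changed 2-fold, with 2 false calls. For the difference between the mouse Dux and human DUX4 responses it recovered 64% and 86%, with 2 false calls. For luciferase, with 0 genes changed, it made 0 false calls. DESeq2 recovered 86% and 93% for mouse Dux induction over 13602 genes, with 10 false calls. The list test called 4 of 4 lists shifted 1.3-fold and 0 of the others, over 13042 genes. Simulated genes were drawn independently of each other, so false list calls from correlated genes were not tested. Each simulated gene had the same spread in every group. The larger spread within the real mouse Dux groups was not simulated, so these rates may not hold for the real libraries. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9 was used for tables and plots.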

Results

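RNA-seq read counts were compared across 18 libraries of C2C12 mouse myoblasts, in 6 groups of 3 separate cultures. Each of 3 clonal lines, carrying inducible mouse Dux, human DUX4 or luciferase, was measured with doxycycline (induced, 36 h) and without it (uninduced). The mouse Dux libraries held 16958640, 14669228 and 15235481 counts when induced and 11010586, 16208714 and 14714757 when uninduced. The human DUX4 libraries held 14419965, 15271395 and 15020182 counts when induced and 15743008, 15238304 and 12871469 when uninduced. The luciferase libraries held 15811645, 15244162 and 16500391 counts when induced and 17179642, 16372351 and 14418920 when uninduced. The 10 most abundant genes took 13.0% ± 0.712 of the counts in induced mouse Dux libraries (SD, n = 3) and group means between 3.99% and 6.21% in the other groups. Values below are CPM as mean ± SD (n = 3) and log2 fold changes from edgeR, with positions in GRCm38 (mm10).

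The first question was which genes changed when mouse Dux was switched on in myoblasts. Among the named genes with the largest rises were genes of the 2-cell embryo. BC080695, which is not on the 2-cell-stage list, also rose, from 0.941 ± 0.221 to 4609 ± 441 CPM. Zscan4c, a zinc finger gene of that stage (Entrez 245109, chromosome 7, 11005745 to 11010547), went from 3.33 ± 0.506 to 18694 ± 609 CPM, a log2 fold change of 12.47 (SE 0.108, adjusted p = 8.94e-24). Pramef25 of the Prame family (chromosome 4, 143948580 to 143951016) went from 0.738 ± 0.18 to 3357 ± 285 CPM (12.18, SE 0.116). The deubiquitinase gene Usp17la (chromosome 7, 104857009 to 104862667) rose from 1.298 ± 0.379 to 1102 ± 35.8 CPM (9.72, SE 0.1), and Tcstv1 rose to 241 ± 31.1 CPM (11.27, SE 0.219). Zscan4d and Zscan4f rose by 12.65 and 12.55. The few uninduced Zscan4 counts may be reads of induced libraries assigned to others of a pool. The Zscan4 folds may therefore be lower bounds. Near-identical copies make the split of reads within the Zscan4, Usp17l and Pramef families uncertain. The 5 Zscan4 genes summed took 5.88% ± 0.144 of all counts in induced libraries and 0.00126% ± 0.000314 in uninduced ones.

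Slc34a2, a phosphate transporter gene (chromosome 5, 53038081 to 53071664), held 2534 counts after mouse Dux induction and 1 count before it, a ratio of 2686 (95% exact interval 482 to 106145). Without uninduced mouse Dux library 1, which held that count, its fitted log2 fold change of 10.94 became 12.85. The embryonic zinc finger gene Zfp352 held 1512 counts against 1, a ratio of 1603 (95% exact interval 287 to 63352), and its fitted change of 10.20 became 12.08 without uninduced library 3. The endogenous Dux gene (chromosome 10, 58229979 to 58232675) held 71 counts against 3, a ratio of 25.1 (95% exact interval 8.24 to 125), and its fitted change of 4.49 became 5.24 without uninduced library 2. Whether reads of the codon-altered transgene were counted at that gene was not analysed here.

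The pro-apoptotic p53 target Pmaip1 (chromosome 18, 66458533 to 66465565) went from 5.35 ± 0.468 to 797 ± 56.7 CPM (7.23, SE 0.119, adjusted p = 3.17e-20) with mouse Dux. The heat-inducible chaperone gene Hspa1a (chromosome 17, 34969190 to 34972156) went from 30.7 ± 1.05 to 1431 ± 136 CPM (5.54, SE 0.0747), with reads possibly shared with its near-identical copy Hspa1b (5.05). The immediate early transcription factor genes Fos and Atf3 rose by 5.36 (SE 0.161) and 6.26 (SE 0.189). Among the largest falls were Sfrp2, a secreted modulator of Wnt signalling (chromosome 3, 83766321 to 83774316), from 311 ± 13.2 to 10.9 ± 2.5 CPM (−4.83, SE 0.103), Cilp, a cartilage matrix gene (−5.44, SE 0.216), and Igf1, encoding a growth factor (−4.01, SE 0.155). The cell-cycle inhibitor gene Cdkn1a (chromosome 17, 29090976 to 29100727) fell from 248 ± 4.79 to 89.5 ± 4.72 CPM (−1.47, SE 0.0496), and the myoblast determination gene Myod1 (chromosome 7, 46376474 to 46379099) from 123 ± 6.11 to 88.1 ± 10.6 CPM (−0.48, SE 0.0768, adjusted p = 1.85e-05). Of 13602 genes tested, 4643 rose and 4728 fell, of which 931 and 278 changed strongly. With library size alone in place of TMM, the median of all genes shifted by −0.24 and the calls became 3199 higher and 6922 lower, a higher share of 31.6% against 49.5%. Changes are given relative to the TMM scaling.

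**Figure D1:**
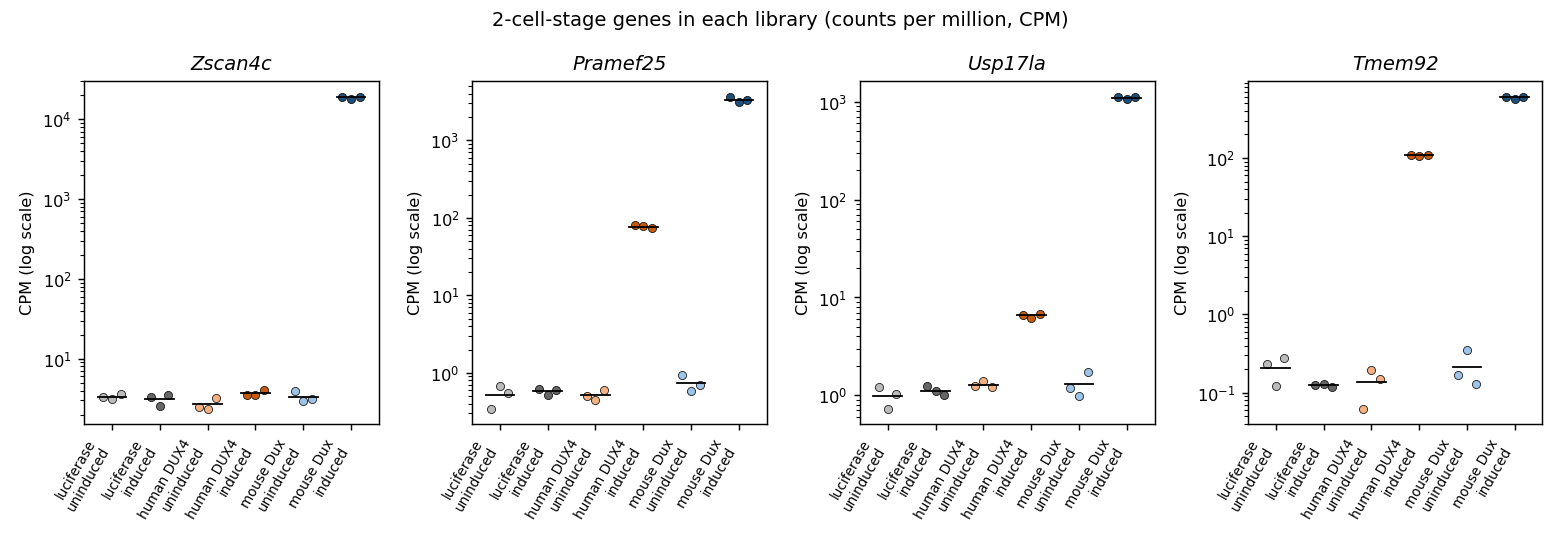
CPM on a log axis of Zscan4c, Pramef25, Usp17la and Tmem92 in the 6 groups, with a point for each of 3 libraries per group and a line at the group mean. Zscan4c reached 18694 CPM in induced mouse Dux libraries against 3.71 CPM in induced human DUX4 libraries.

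Of the gene lists, 13 of 20 passed the camera test after mouse Dux induction. In the 20 list tests of each of the 4 planned comparisons, counts adjusted over the list alone equalled those over all genes unless given. Of 45 measured 2-cell-stage genes 44 rose and 0 fell, with a median log2 fold change of 11.11 (10.26 with 18 genes at their counting bound, adjusted p = 1.88e-197). Of 16 mouse counterparts of human DUX4 targets 15 rose and 1 fell (median 3.93, or 4.01 at the bound, adjusted p = 3.64e-25). Zscan4c, Pramef6 and Pramef25 are among the genes on both lists, so these 2 tests are not separate evidence. All 25 cholesterol synthesis genes fell (median −1.29, adjusted p = 5.26e-23), among them Fdps (−2.39, SE 0.0641) and Idi1 (−2.04, SE 0.0572), which encode enzymes of the mevalonate pathway. Of 9 adipocyte and osteoblast markers 5 rose and 1 fell (median 0.70, adjusted p = 0.00717), including the matrix protein gene Spp1 (2.17, SE 0.0545) and the transcription factor gene Cebpa (2.21). These 4 lists also passed with an estimated correlation, at adjusted p = 1.51e-05, 1.65e-05, 0.00314 and 0.0482.

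Several lists rose after mouse Dux induction with the preset correlation only. Of 34 integrated stress and unfolded protein response genes 26 rose and 2 fell (median 0.91, adjusted p = 8.01e-06; adjusted p = 0.254 with an estimated correlation). Heat shock genes rose in 15 of 20 cases and fell in 2 (median 0.46, adjusted p = 7.86e-08; adjusted p = 0.0642 with an estimated correlation). Of 25 immediate early genes 21 rose and 2 fell, or 22 and 2 adjusted over the list alone (median 1.57, adjusted p = 1.07e-10; adjusted p = 0.0732 with an estimated correlation). Of 10 pluripotency genes tested, out of 25 matched, 6 rose and 0 fell (median 1.84, or 1.62 at the bound, adjusted p = 0.00674). They included Klf5, Klf2 and Klf4, which encode Krüppel-like factors (2.09, 2.55 and 1.62). Klf2 is also on the immediate early list. The pluripotency list had adjusted p = 0.0642 with an estimated correlation. Of 12 double-homeobox and PRD-like genes 7 rose and 3 fell, or 7 and 4 adjusted over the list alone (median 5.63, or 4.63 with 7 genes at the bound, adjusted p = 0.0168). This call ended at adjusted p = 0.324 with an estimated correlation, at 0.193 without induced mouse Dux library 1, at 0.0528 without the filter on low counts, and at 0.113 in the replicate block.

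Apart from cholesterol synthesis genes, the lists that fell after mouse Dux induction passed with the preset correlation only. Of 28 myogenic genes 8 rose and 17 fell (median −0.49, or −0.56 at the bound, adjusted p = 0.0149; adjusted p = 0.0955 with an estimated correlation), with Cdh15, a myoblast cadherin gene, at −1.80 (SE 0.058). Of 50 G2 and M-phase genes 3 rose and 37 fell, or 3 and 39 adjusted over the list alone (median −0.43, adjusted p = 0.00115; adjusted p = 0.304 with an estimated correlation). The mitotic kinesin gene Kif11 fell from 139 ± 6.65 to 72.2 ± 4.07 CPM (−0.94, SE 0.0582). Collagen and matrix genes rose in 8 and fell in 21 of 32 cases (median −0.82, adjusted p = 0.00865; adjusted p = 0.367 with an estimated correlation), with the metalloprotease gene Mmp2 at −2.15 and the matricellular gene Cyr61 at 3.09. Of 39 sarcomere genes 2 rose and 21 fell, or 2 and 20 adjusted over the list alone (median −1.24, or −0.88 at the bound, adjusted p = 0.0442; adjusted p = 0.367 with an estimated correlation). That call also ended without induced mouse Dux library 2 (adjusted p = 0.0580) or 3 (adjusted p = 0.05001) and with library size alone (adjusted p = 0.239). Troponin gene Tnnt1 fell (−3.08, SE 0.106) while the myosin light chain gene Myl1 rose (4.87, SE 0.208).

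The other 7 lists did not pass after mouse Dux induction. P53 targets went both ways, with 13 of 31 higher and 12 lower (median 0.01, adjusted p = 0.207). Interferon-stimulated genes were higher in 11 and lower in 2 of 23, or 10 and 2 adjusted over the list alone (median 0.28, or 0.26 at the bound, adjusted p = 0.412). S-phase genes were higher in 18 and lower in 7 of 45 (median 0.11, adjusted p = 0.559), and chromatin repressors in 13 and 6 of 30, or 13 and 5 adjusted over the list alone (median 0.16, adjusted p = 0.468). Nonsense-mediated decay and splicing factor genes were higher in 14 and lower in 11 of 37 (adjusted p = 0.821), with a median of −0.000341 and a mean of 0.07. Of 5 germline genes 1 was higher and 1 lower, or 0 and 0 adjusted over the list alone (median 0.08 with the test direction down, adjusted p = 0.974). Of 10 markers of other cell types 4 were higher and 2 lower (median 0.26, or 0.25 at the bound, adjusted p = 0.974).

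The second question was how the human factor acted on the same mouse background. Human DUX4 raised genes that were near 0 in the uninduced line. Tmem92, a transmembrane protein gene on the 2-cell list (chromosome 11, 94777217 to 94782703), went from 0.135 ± 0.0663 to 108 ± 3.14 CPM, a log2 fold change of 9.57 (SE 0.130, adjusted p = 1.91e-20). Uts2, encoding the peptide urotensin (chromosome 4, 150997097 to 151001810), went from 0.177 ± 0.0696 to 77.0 ± 1.7 CPM (8.69, SE 0.173). The placental protease gene Ctsq went from no count in any of the 3 uninduced libraries to 13.5 ± 0.901 CPM, at least 202-fold higher. C8b, Pcp4 and Gad1 had likewise no uninduced count and were at least 125-, 85.1- and 77.0-fold higher. Pramef25 rose from 0.518 ± 0.0788 to 77.4 ± 3.57 CPM (7.21, SE 0.128), and the Notch effector gene Hey1 from 4.35 ± 0.713 to 88.6 ± 2.18 CPM (4.35, SE 0.12). Cdkn1a rose from 131 ± 3.16 to 847 ± 29.5 CPM (2.69, SE 0.0503, adjusted p = 7.38e-19).

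Spp1 (chromosome 5, 104435118 to 104441050) fell with human DUX4 from 1111 ± 19.9 to 44.8 ± 2.74 CPM (−4.63, SE 0.0622). Other falls were Insc (−6.01, SE 0.229), which acts in spindle orientation, the metabolic kinase gene Pdk4 (−4.83, SE 0.103), and the collagen gene Col1a2, from 2378 ± 31.7 to 264 ± 5.37 CPM (−3.17, SE 0.0624). Myod1 fell from 26.2 ± 0.403 to 3.67 ± 0.907 CPM (−2.84, SE 0.124). The acetylcholine receptor subunit gene Chrnd rose from 21.9 ± 1.33 to 168 ± 3.85 CPM (2.94, SE 0.054). Zscan4c measured 2.71 ± 0.47 CPM before and 3.71 ± 0.325 CPM after induction (0.47, SE 0.14, adjusted p = 0.0103), a call lost without induced human DUX4 library 3 (0.39, adjusted p = 0.0649) or uninduced library 2 (0.38, adjusted p = 0.0676). Usp17la rose from 1.29 ± 0.107 to 6.55 ± 0.317 CPM (2.33, SE 0.145, adjusted p = 2.47e-11). Slc34a2 and Ccna1 had no count in these libraries. Of 13602 genes 4683 rose and 4508 fell, of which 593 and 521 changed strongly.

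Cell-cycle genes fell after human DUX4 induction. Of 45 S-phase genes 1 rose and 43 fell (median −1.75, adjusted p = 1.66e-27), and of 50 G2 and M-phase genes 0 rose and 49 fell (median −2.16, adjusted p = 5.47e-48). The replication helicase gene Mcm3 (chromosome 1, 20802968 to 20820312) fell from 148 ± 2.77 to 26.4 ± 0.788 CPM (−2.49, SE 0.0512), and Kif11 from 159 ± 4.65 to 24.6 ± 1.63 CPM (−2.70, SE 0.064). Both lists also passed with an estimated correlation, at adjusted p = 6.91e-05 and 0.000337. Of 25 cholesterol synthesis genes 1 rose and 22 fell (median −0.75, adjusted p = 1.02e-08; adjusted p = 0.0642 with an estimated correlation), with the lanosterol synthase gene Lss at −1.67. Collagen and matrix genes rose in 7 and fell in 24 of 32 cases (median −0.84, adjusted p = 5.38e-08; adjusted p = 0.107 with an estimated correlation). Of 31 p53 targets 20 rose and 8 fell (median 0.63, adjusted p = 0.00310; adjusted p = 0.0688 with an estimated correlation), with Plk3, a stress kinase gene, at 3.42. Of 45 2-cell-stage genes 20 rose and 0 fell, or 17 and 0 adjusted over the list alone (median 0.94, adjusted p = 0.00818; adjusted p = 0.272 with an estimated correlation). With 8 of them at the bound and 14 left out for holding at most 3 counts in both groups, that median was 0.75.

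Calls on a pair of lists rested on single libraries after human DUX4 induction. Of 37 nonsense-mediated decay and splicing factor genes 5 rose and 24 fell (median −0.25, adjusted p = 0.0471; adjusted p = 0.236 with an estimated correlation). That call ended without induced human DUX4 library 1 (adjusted p = 0.0549) or 3 (0.0509), without uninduced library 1 (0.0514) or 3 (0.0536), and with median-of-ratios scaling (0.0518). Of 9 adipocyte and osteoblast markers 3 rose and 3 fell (median −1.12, or −0.97 at the bound, adjusted p = 0.0455; adjusted p = 0.107 with an estimated correlation). That call ended without induced library 1 (−1.33, adjusted p = 0.0579) or 3 (−0.58, adjusted p = 0.0559), without the filter on low counts (−0.15, adjusted p = 0.462) and in the replicate block (adjusted p = 0.565). Interferon-stimulated genes were higher in 12 and lower in 0 of 23, or 11 and 0 adjusted over the list alone (median 0.50, or 0.55 at the bound, adjusted p = 0.0677), with Ifit3 at 3.91 (SE 0.237). They passed without uninduced library 1 (adjusted p = 0.0499), without the filter on low counts (0.0150) and in the replicate block (0.0201).

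The other 11 lists did not pass after human DUX4 induction. Counterparts of human DUX4 targets were higher in 8 and lower in 2 of 16 (median 1.40, or 1.61 at the bound, adjusted p = 0.0711; 0.0144 with only the groups compared in the fit). Chromatin repressors were higher in 7 and lower in 18 of 30 (median −0.31, adjusted p = 0.0868), passing in the replicate block (0.0456) and without the filter on low counts (0.0162). Immediate early genes were higher in 8 and lower in 14 of 25 (median −0.60, adjusted p = 0.142), with the growth regulator Myc at −2.21. Sarcomere genes were higher in 7 and lower in 8 of 39 (median −0.66, or −0.68 at the bound, adjusted p = 0.404), with Tnnt2 at −4.31. Pluripotency genes were higher in 3 and lower in 2 of 10 (median 0.89, or 1.07 at the bound, adjusted p = 0.391). Lists whose median and test differed in sign were myogenic genes (10 higher and 11 lower of 28, median −0.18, or −0.06 at the bound, mean 0.01, adjusted p = 0.614), integrated stress genes (14 and 14 of 34, median −0.15, or −0.16 at the bound, mean 0.30, adjusted p = 0.820) and heat shock genes (7 and 9 of 20, or 7 and 10 adjusted over the list alone, median −0.09, mean 0.10, adjusted p = 0.692). Double-homeobox genes were higher in 2 and lower in 2 of 12 (median −0.04, or −0.40 at the bound, adjusted p = 0.893), germline genes in 1 and 1 of 5 (median 0.88, adjusted p = 0.893), and markers of other cell types in 3 and 2 of 10 (median 0.02, or −0.05 at the bound, adjusted p = 0.793).

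The luciferase line, induced to make an unrelated protein, was the control. Proliferation genes fell in it. Kif11 (chromosome 19, 37376403 to 37421859) went from 35.8 ± 1.11 to 4.48 ± 0.57 CPM (−3.00, SE 0.0861, adjusted p = 7.63e-15), the mitotic checkpoint gene Bub1 from 24.7 ± 0.424 to 2.91 ± 0.121 CPM (−3.08, SE 0.0823), and Mcm3 from 16.7 ± 0.549 to 3.55 ± 0.236 CPM (−2.23, SE 0.08). Neil3, a DNA repair glycosylase gene, and the mitotic kinase gene Aurkb fell as well (−3.79, SE 0.234, and −3.34, SE 0.165). The adhesion receptor gene Adgrg1 rose from 10.2 ± 0.863 to 89.4 ± 0.074 CPM (3.14, SE 0.0846) and the protease inhibitor gene Serpinb9g from 0.435 ± 0.0456 to 11.2 ± 2.18 CPM (4.66, SE 0.258). Of 13602 genes 2004 rose and 2224 fell, of which 36 and 134 changed strongly. Zscan4c (−0.09, adjusted p = 0.737), Usp17la (0.17, adjusted p = 0.711) and Cdkn1a (0.04, adjusted p = 0.53) did not pass. Myog, which drives myotube formation, fell from 194 ± 5.83 to 118 ± 5.81 CPM (−0.72, SE 0.0829).

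In the luciferase line 9 of 20 lists passed. Of 50 G2 and M-phase genes 1 rose and 48 fell (median −2.41, adjusted p = 1.53e-168), and of 45 S-phase genes 0 rose and 40 fell (median −0.99, adjusted p = 2.09e-34). All 25 cholesterol synthesis genes fell (median −1.16, adjusted p = 1.43e-58), with Idi1 (chromosome 13, 8885501 to 8892451) going from 88.6 ± 0.631 to 21.5 ± 2.1 CPM (−2.04, SE 0.0624). Of 39 sarcomere genes 1 rose and 30 fell, or 1 and 33 adjusted over the list alone (median −0.68, adjusted p = 1.86e-26), with the cardiac actin gene Actc1 at −2.03 (SE 0.0825). Of 28 myogenic genes 3 rose and 18 fell, or 3 and 21 adjusted over the list alone (median −0.35, adjusted p = 7.07e-07). These 5 lists also passed with an estimated correlation, at adjusted p = 1.19e-06, 1.65e-05, 3.56e-05, 0.000558 and 0.00245. Heat shock genes fell in 17 of 20 cases and rose in 0 (median −0.35, adjusted p = 7.26e-07; adjusted p = 0.0690 with an estimated correlation). Of 34 integrated stress genes 22 rose and 8 fell, or 24 and 8 adjusted over the list alone (median 0.61, adjusted p = 9.6e-10; adjusted p = 0.125 with an estimated correlation), with Ddit3, a stress transcription factor gene, at 1.90 (SE 0.103). Collagen and matrix genes rose in 6 and fell in 18 of 32 cases, or 6 and 19 adjusted over the list alone (median −0.37, adjusted p = 0.00169; adjusted p = 0.310 with an estimated correlation). Of 31 p53 targets 15 rose and 4 fell, or 17 and 5 adjusted over the list alone (median 0.19, adjusted p = 0.0255; adjusted p = 0.141 with an estimated correlation).

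The other 11 lists did not pass in the luciferase line. The 2-cell-stage genes were higher in 6 and lower in 0 of 45, or 5 and 0 adjusted over the list alone (median 0.00, or 0.03 at the bound, adjusted p = 0.217; 0.0154 with only the groups compared in the fit). Immediate early genes were higher in 8 and lower in 5 of 25 (median 0.04, adjusted p = 0.0593) and pluripotency genes in 3 and 0 of 10 (median 3.89e-05, or 7.78e-05 at the bound, adjusted p = 0.130). Without induced luciferase library 2 both passed, at 0.05 (adjusted p = 0.0295) and 0.06 (adjusted p = 0.0423). Adipocyte and osteoblast markers were higher in 4 and lower in 0 of 9 (median 0.34, adjusted p = 0.0642) and passed in the replicate block (0.0178). Splicing factor genes were higher in 3 and lower in 15 of 37, or 3 and 18 adjusted over the list alone (median −0.08, adjusted p = 0.130), and also passed in the replicate block (0.0406). Both of these passed with only the groups compared (0.0422 and 0.0457) and without the filter on low counts (0.0491 and 0.0142). Chromatin repressors were higher in 3 and lower in 9 of 30, or 5 and 11 adjusted over the list alone (median −0.01, adjusted p = 0.224). Interferon-stimulated genes were higher in 1 and lower in 2 of 23, or 0 and 0 adjusted over the list alone (median −0.09, or −0.01 at the bound, adjusted p = 0.820). Counterparts of human DUX4 targets were higher in 2 and lower in 0 of 16, or 1 and 0 adjusted over the list alone (adjusted p = 0.884), double-homeobox genes in 0 and 2 of 12 (median −0.00168, or −0.12 at the bound, adjusted p = 0.597), germline genes in 0 and 0 of 5 (adjusted p = 0.974) and markers of other cell types in 0 and 1 of 10 (median −0.12, or −0.16 at the bound, adjusted p = 0.250). For 4 lists the test direction was up while the mean was negative: 2-cell-stage genes (mean −0.16), counterparts of human DUX4 targets (median −0.00395, or −0.00410 at the bound, mean −0.18), pluripotency genes (mean −0.02) and germline genes (median 0.03, or 0.05 at the bound, mean −0.41).

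**Figure D2:**
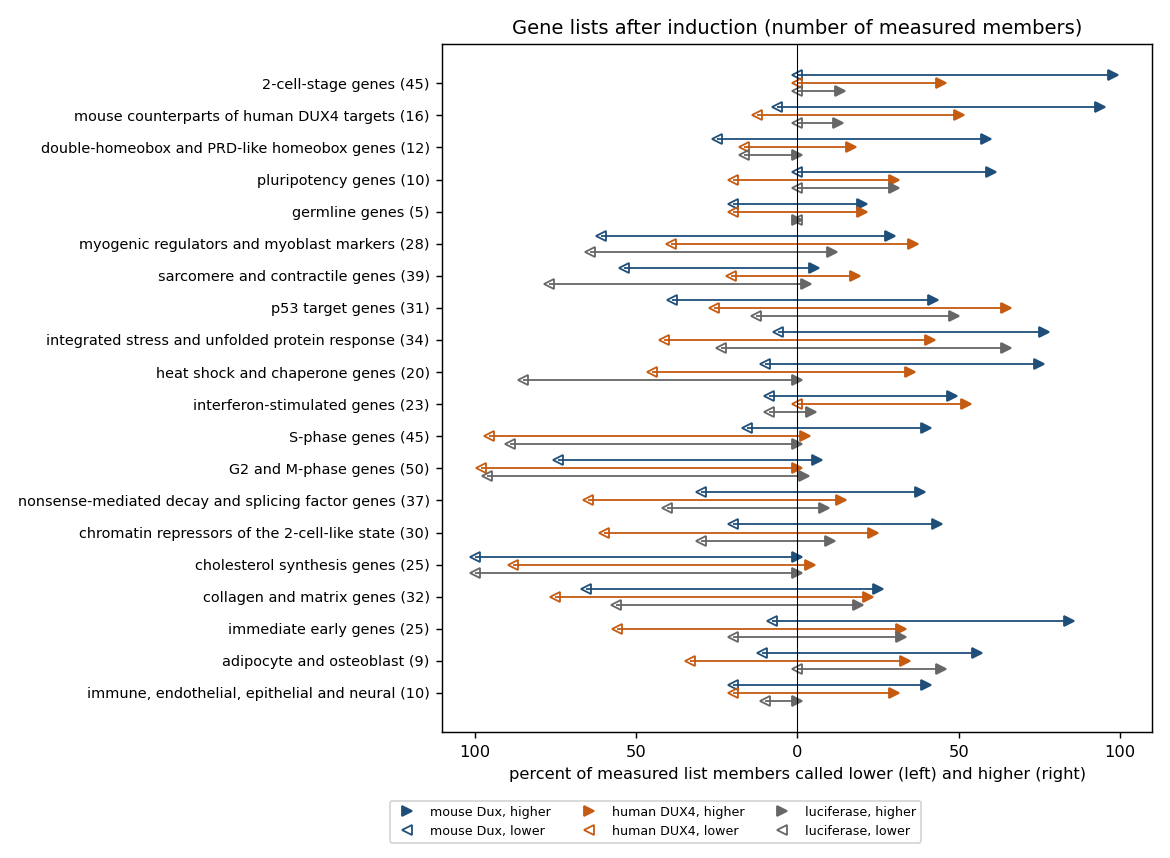
Percent of the measured members of each gene list called lower (left, open) and higher (right, filled) after induction of mouse Dux (blue), human DUX4 (orange) or luciferase (grey). Of 25 cholesterol synthesis genes 25, 22 and 25 were called lower in the 3 lines.

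To set each factor against the control protein, the luciferase response was subtracted in the same model. Cell-cycle genes, which fell in the luciferase line, then stood higher with mouse Dux: 44 of 50 G2 and M-phase genes had a higher response than with luciferase and 3 a lower one (median difference 1.99, adjusted p = 1.26e-24), as did 40 and 1 of 45 S-phase genes (1.16, adjusted p = 2.84e-11). The 2-cell-stage genes differed in 36 of 45 cases (median 11.40, adjusted p = 2.20e-26) and heat shock genes were higher in 18 and lower in 1 of 20 (0.83, adjusted p = 1.07e-16). Counterparts of human DUX4 targets (4.02, adjusted p = 0.00134) passed too. These 5 lists also passed with an estimated correlation, at adjusted p = 0.00437, 0.00210, 0.00210, 0.00914 and 0.0138. Immediate early genes (1.32, adjusted p = 2.42e-09) and integrated stress genes (0.50, adjusted p = 0.0222) passed with the preset correlation only (0.107 and 0.570 with an estimated one). Cholesterol synthesis genes (−0.36, adjusted p = 0.0645), sarcomere genes (−0.55, adjusted p = 0.780), myogenic genes (0.000803, adjusted p = 0.462), collagen genes (−0.31, adjusted p = 0.294), adipocyte and osteoblast markers (1.26, adjusted p = 0.0645; 0.177 with an estimated correlation), pluripotency genes (1.63, adjusted p = 0.184) and double-homeobox genes (5.30, adjusted p = 0.780) lost the calls they had after mouse Dux induction.

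For human DUX4 with the luciferase response subtracted, the G2 and M-phase difference was 0.08 (20 higher and 11 lower of 50, adjusted p = 0.974, with the test direction down). S-phase genes lay lower by −0.32 (adjusted p = 0.0124, or 0.177 with an estimated correlation) and collagen genes by −0.66 (adjusted p = 4.93e-06, or 0.177 with an estimated correlation). The 2-cell-stage genes, with 12 higher and 0 lower of 45 (1.08, adjusted p = 0.275), cholesterol synthesis genes (0.34, adjusted p = 0.0645) and splicing factor genes (−0.21, adjusted p = 0.203) lost their calls, as G2 and M-phase genes did. P53 targets (14 higher and 9 lower of 31, 0.23, adjusted p = 0.00770), heat shock genes (11 and 6 of 20, 0.28, adjusted p = 0.00819) and immediate early genes (7 and 11 of 25, −0.62, adjusted p = 0.0182) passed, though not with an estimated correlation (0.107, 0.335 and 0.545). Adipocyte and osteoblast markers were higher in 3 and lower in 4 of 9 (−1.36, adjusted p = 0.000960; 0.0138 with an estimated correlation). The list tests with the luciferase response subtracted were chosen after that response was seen. By gene, the mouse Dux response exceeded the luciferase response for 4139 genes and lay below it for 4017. The human DUX4 response exceeded it for 3856 and lay below it for 3631. With library size alone the mouse Dux difference split into 2832 and 5972, a higher share of 32.2% against 50.7%, after a median shift of −0.26.

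The difference between the mouse and the human factor was tested directly. Zscan4c responded more to mouse Dux by 12.01 (SE 0.226, adjusted p = 1.61e-18), Usp17la by 7.39 (SE 0.27) and Pramef25, which rose with both, by 4.96 (SE 0.373). Zscan4c counts outside induced mouse Dux libraries may be misassigned reads, so its difference may depend on them. Several genes went opposite ways. Spp1 rose with mouse Dux to 1548 ± 114 CPM and fell with human DUX4 to 44.8 ± 2.74 CPM, a difference of 6.81 (SE 0.0823, adjusted p = 4.24e-21). Cdkn1a fell with mouse Dux and rose with human DUX4 (−4.16, SE 0.0704). Pmaip1 reached 797 ± 56.7 CPM with mouse Dux and 6.28 ± 1.61 CPM with human DUX4 (8.17, SE 0.18), and Hspa1a 1431 ± 136 against 15.8 ± 1.42 CPM (6.396, SE 0.104). Nrap, a myofibril assembly gene, and Chrnd responded more to human DUX4 (−8.80, SE 0.173, and −3.54, SE 0.0809). Myod1 differed by 2.36 (SE 0.149) and Mcm3 by 2.85 (SE 0.0705). Myog did not pass (−0.61, adjusted p = 0.389) but did without induced mouse Dux library 1 (−1.65, adjusted p = 0.0229). The response was higher with mouse Dux for 4471 genes and lower for 4397, of which 922 and 511 differed strongly. With library size alone the split was 3538 and 5582, a higher share of 38.8% against 50.4%, after a median shift of −0.20.

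Genes with no count in one group are poorly served by this difference test. Of 654 such genes edgeR called 116 and limma-voom, chosen after the data were seen, called 401. Slc34a2, at 60.2 ± 3.36 CPM with mouse Dux and 0 counts with human DUX4, had adjusted p = 1 in edgeR, 1.31e-07 in DESeq2 and 7.74e-10 in limma-voom. Usp17lc, at 190 ± 14.8 CPM with mouse Dux and 1 count with human DUX4, had adjusted p = 0.999, 2.85e-07 and 1.65e-08. Among 45 2-cell-stage genes edgeR called 31 higher with mouse Dux and limma-voom 44.

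**Figure D3:**
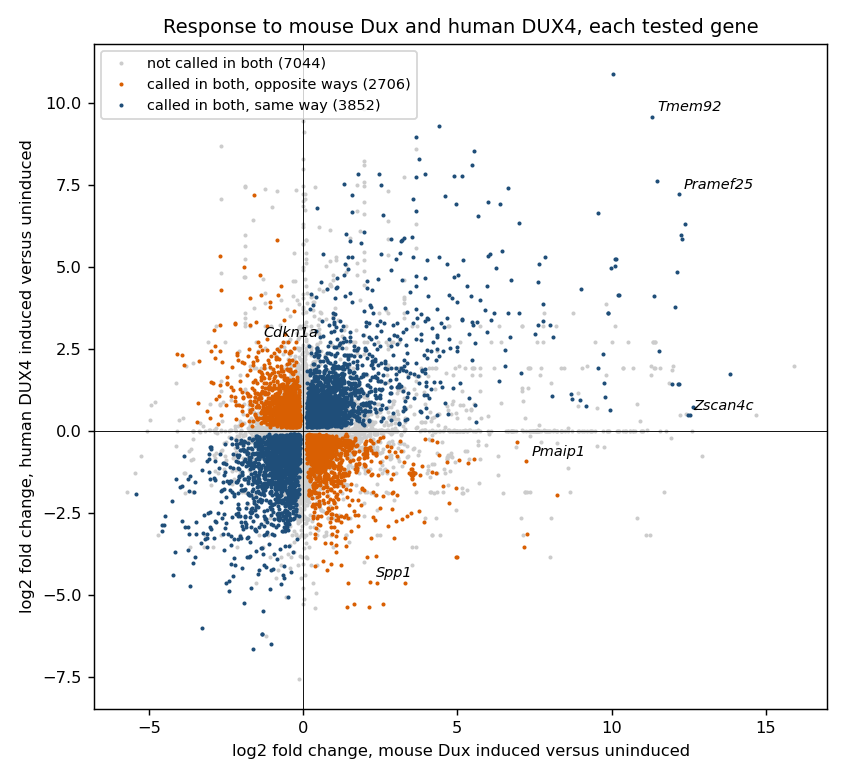
Log2 fold change after mouse Dux induction (x axis) and after human DUX4 induction (y axis), one point per tested gene, with blue for 3852 genes called the same way in both, orange for 2706 called opposite ways and grey for 7044 not called in both. Labels mark Tmem92, Pramef25, Zscan4c, Cdkn1a, Pmaip1 and Spp1.

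By list, the response to mouse Dux was higher for 2-cell-stage genes (31 higher and 0 lower of 45, median difference 8.84, adjusted p = 4.97e-14; adjusted p = 0.00616 with an estimated correlation), S-phase genes (42 and 1 of 45, 1.83, adjusted p = 2.92e-25; adjusted p = 1.65e-05 with an estimated correlation) and G2 and M-phase genes (47 and 0 of 50, 1.80, adjusted p = 2.13e-25; adjusted p = 0.00300 with an estimated correlation). Lists with a group at 0 counts have medians that depend on the prior count of the fit. Immediate early genes were higher in 23 and lower in 2 of 25 (1.71, adjusted p = 2.63e-11; adjusted p = 0.0608 with an estimated correlation), with Myc at 3.22 (SE 0.102). Heat shock genes were higher in 15 and lower in 5 of 20 (0.67, adjusted p = 1.39e-05; adjusted p = 0.108 with an estimated correlation) and stress response genes in 23 and 2 of 34 (0.76, adjusted p = 0.000223; adjusted p = 0.312 with an estimated correlation), with the chaperone gene Hspa5 at 1.70. Collagen and matrix genes were higher in 19 and lower in 9 of 32, or 20 and 9 adjusted over the list alone (0.99, adjusted p = 0.00304; adjusted p = 0.312 with an estimated correlation). Chromatin repressors were higher in 17 and lower in 6 of 30 (0.40, adjusted p = 0.0227; adjusted p = 0.0679 with an estimated correlation). Cholesterol synthesis genes were lower in 18 and higher in 3 of 25, or 19 and 4 adjusted over the list alone (−0.64, adjusted p = 0.000385; adjusted p = 0.199 with an estimated correlation), with Idi1 at −1.67.

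The remaining calls between mouse Dux and human DUX4 were fragile. Adipocyte and osteoblast markers were higher in 4 and lower in 1 of 9 (1.41, adjusted p = 8.01e-05; adjusted p = 0.00532 with an estimated correlation), with adjusted p = 0.0552 without induced mouse Dux library 1, 0.0956 without the filter on low counts and 0.102 in the replicate block. Counterparts of human DUX4 targets were higher in 8 and lower in 1 of 16 (4.38, adjusted p = 0.0357; adjusted p = 0.0832 with an estimated correlation). That call ended without induced mouse Dux library 1 (adjusted p = 0.105), 2 (0.0548) or 3 (0.0599), without uninduced human DUX4 library 1 (0.0505), without the filter on low counts (0.0551), and in the replicate block (0.0555). Splicing factor genes were higher in 19 and lower in 4 of 37 (0.30, adjusted p = 0.0422; adjusted p = 0.223 with an estimated correlation), a call that ended with library size alone (0.09, adjusted p = 0.126) and with only the groups compared (adjusted p = 0.0647). Myogenic genes (7 higher and 13 lower of 28, −0.55, adjusted p = 0.0565) passed only with the groups compared alone (−0.62, adjusted p = 0.0365). P53 targets (9 and 13 of 31, −0.15, adjusted p = 0.230), pluripotency genes (5 and 1 of 10, 1.76, adjusted p = 0.224), interferon-stimulated genes (5 and 8 of 23, or 5 and 7 adjusted over the list alone, −0.30, adjusted p = 0.597) and sarcomere genes (6 and 9 of 39, or 6 and 8 adjusted over the list alone, −0.93, adjusted p = 0.801) did not pass. Neither did double-homeobox genes (3 and 3 of 12, adjusted p = 0.850), germline genes (0 and 1 of 5, or 0 and 0 adjusted over the list alone, adjusted p = 0.921) and markers of other cell types (3 and 1 of 10, median 0.23, mean −0.11, adjusted p = 0.745).

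The overlap of the mouse Dux and human DUX4 responses was counted by direction, with no library shared between them. The luciferase response was not subtracted here, so changes that also occur with the control protein are included. In both responses 1851 genes rose, against 1599 for independent lists (odds ratio 1.43), and 2001 fell, against 1567 (odds ratio 1.86). Two-sided Fisher's exact tests gave p = 1.16e-21 and 6.76e-61 over genes, which are not independent replicates. Strongly changed in both were 185 higher genes, against 40.6, and 65 lower genes, against 10.6. Opposite calls were 1266 genes higher with mouse Dux and lower with human DUX4, against 1539, and 1440 the other way, against 1628. Across 13602 genes the log2 fold changes of mouse Dux and human DUX4 had Pearson's r of 0.248 and Spearman's rho of 0.186. Mouse Dux and luciferase gave 0.0251 and 0.00504, and human DUX4 and luciferase 0.182 and 0.192.

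**Figure D4:**
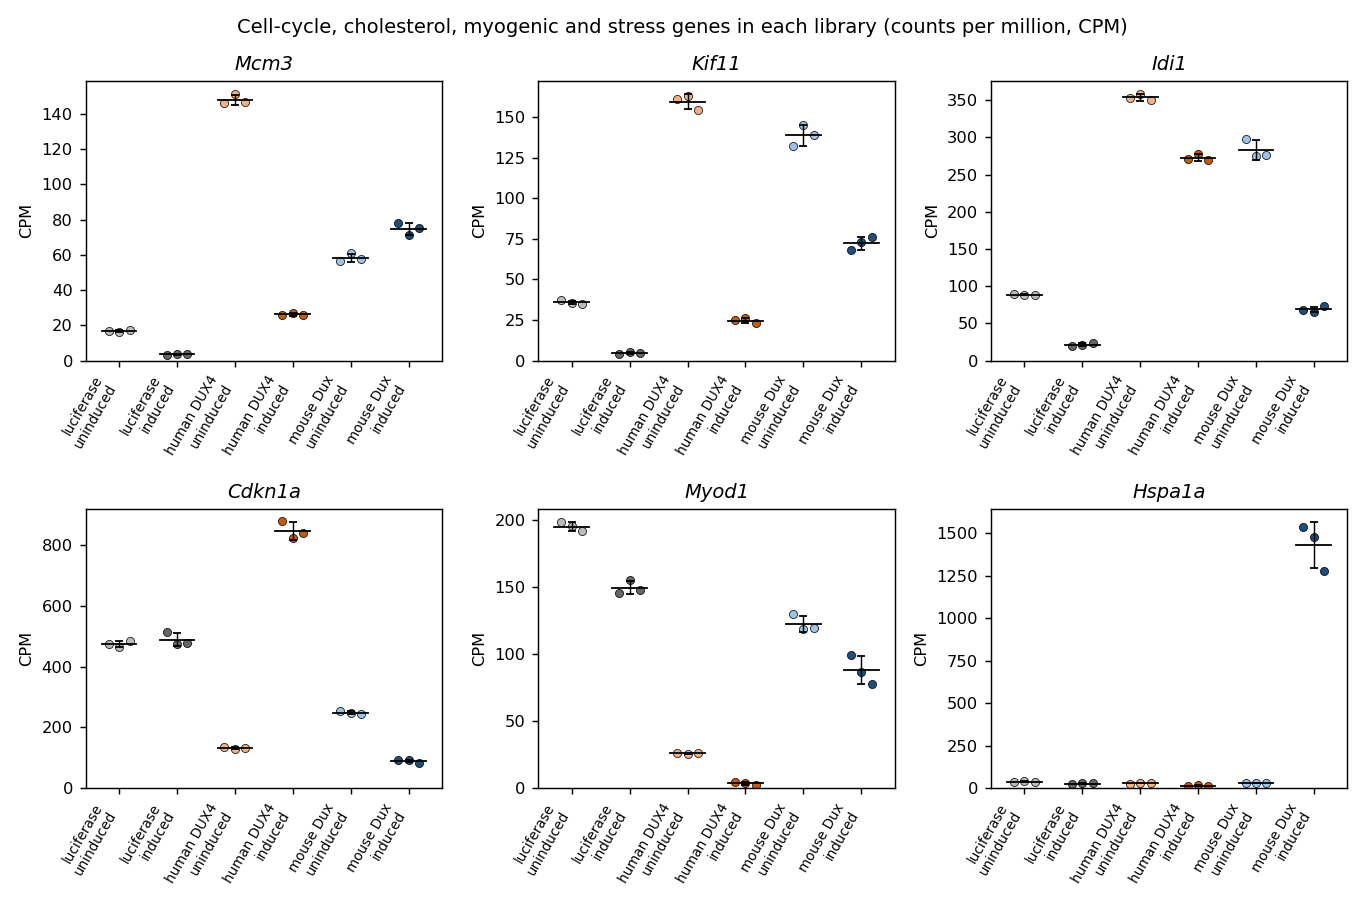
CPM of Mcm3, Kif11, Idi1, Cdkn1a, Myod1 and Hspa1a in the 6 groups, with a point per library and the mean ± SD of 3 libraries. Cdkn1a stood at 89.5 CPM in induced mouse Dux and 847 CPM in induced human DUX4 libraries.

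The uninduced lines were compared to see how far the clones differed at the start. Myog (chromosome 1, 134289989 to 134292548) measured 194 ± 5.83 CPM in the uninduced luciferase line, 2.32 ± 0.612 CPM in the mouse Dux line (−6.34, SE 0.133, adjusted p = 2.13e-18) and 1.24 ± 0.317 CPM in the human DUX4 line (−7.30, SE 0.147). Myod1 measured 195 ± 3.52 CPM in the luciferase line, 123 ± 6.11 CPM in the mouse Dux line (−0.67, SE 0.0748) and 26.2 ± 0.403 CPM in the human DUX4 line (−2.90, SE 0.0846). Cdkn1a was lower than in the luciferase line by −0.93 (SE 0.0476) and −1.85 (SE 0.0491). Kif11 measured 35.8 ± 1.11 CPM in the luciferase line, 139 ± 6.65 CPM in the mouse Dux line and 159 ± 4.65 CPM in the human DUX4 line. Zscan4c did not pass in the mouse Dux line (−0.03, adjusted p = 0.882) or in the human DUX4 line (−0.32, adjusted p = 0.0862), where it passed without uninduced human DUX4 library 3 (−0.45, adjusted p = 0.0323). Usp17la did not pass in either (0.38 in both, adjusted p = 0.224 and 0.217). Against the luciferase line, 4377 genes were higher and 4506 lower in the mouse Dux line, and 4895 higher and 5028 lower in the human DUX4 line. With library size alone the higher share in the mouse Dux line was 57.6% against 49.3%, after a median shift of 0.085. In the human DUX4 line it was 51.0% against 49.3%.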

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

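The tests on low counts of 2-cell-stage genes, on the luciferase response and on induced mouse Dux library 1 were chosen only after those results were seen, while the differences between responses and the splits of the libraries were planned. The results here came up because a test of the difference itself found that 2 lines responded differently to induction. Groups of 3 are too small for a test of single outlying libraries, and none was run.

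The mouse Dux and human DUX4 responses differed in edgeR for 4471 genes with a higher and 4397 with a lower mouse Dux response. Against luciferase, the mouse Dux response was higher for 4139 genes and lower for 4017, and the human DUX4 response higher for 3856 and lower for 3631. Line labels were permuted among the induced and among the uninduced libraries. For each difference 40 arrangements were used, the real one and a random draw from the others, so not all were tried. The real count was 8156 for mouse Dux against luciferase, reached by 1 of 40 with 7958 as the highest other, 7487 for human DUX4 against luciferase, reached by 3 of 40 with 7855 as the highest other, and 8868 for mouse Dux against human DUX4, reached by 2 of 40 with 10425 as the highest other. Of 20 lists adjusted within that last difference 13 passed, reached by 1 of 40, against 9 in the highest other. The uninduced lines themselves differed by 8883, 9923 and 9030 genes in these 3 pairs. Mixed arrangements therefore carry the line difference as spread, and those that exchange all induced labels measure it, so the arrangements did not test chance for the differences of responses.

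By list, the median difference of the mouse Dux and human DUX4 responses (log2) was 8.84 for 2-cell-stage genes, 4.38 for counterparts of human DUX4 targets, 1.83 for S-phase genes, 1.80 for G2 and M-phase genes, 1.71 for immediate early genes and 1.41 for adipocyte and osteoblast markers. It was 0.99 for collagen and matrix genes, 0.76 for stress response genes, 0.67 for heat shock genes, 0.40 for chromatin repressors, 0.30 for splicing factor genes and −0.64 for cholesterol synthesis genes.

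By gene, the difference was 12.08 for Zscan4f, 12.01 for Zscan4c, 11.92 for Zscan4d, 11.90 for Zscan4a, 8.77 for Gm2022 and 7.39 for Usp17la, families in which near-identical copies share reads. Duxbl3 differed by 7.001, or by 7.66 without uninduced mouse Dux library 2. Other named genes with a higher mouse Dux response were Spp1 (6.81), Hspa1a (6.396), Tnnt2 (3.92), Krt14 (3.49), Uhrf1 (3.29), Myc (3.22), Mcm3 (2.85), Klf5 (2.61), Kif2c (2.45), Myod1 (2.36), Hspa5 (1.70) and Srsf6 (1.20). Of these, Tnnt2, Krt14, Kif2c and Myod1 measured lower after induction of either factor, and less so with mouse Dux. A higher human DUX4 response was measured for Nrap (−8.80), Cdkn1a (−4.16), Chrnd (−3.54), Idi1 (−1.67), Ddx58 (−0.93) and Wfdc3 (−8.16, or −7.49 without uninduced mouse Dux library 2). Idi1 measured lower after induction of either factor, and less so with human DUX4.

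Libraries other than the induced mouse Dux ones held a few counts of 2-cell-stage genes. Among 36 genes raised by at least 8 on the log2 scale with at least 10000 induced counts, 13, the Zscan4 copies among them, had a ratio of mean counts per library, other to induced, between 0.0172% and 0.0256%, although their induced counts spanned a 62.2-fold range. Such a common ratio is consistent with reads of the induced mouse Dux libraries assigned to other libraries of a pool, a technical source that may also lie behind the Zscan4c call with human DUX4. If so, the mouse Dux folds of these 13 genes would be lower bounds. Their differences from the human DUX4 response would rest on such reads too. Some of the 36 genes were raised by human DUX4 itself. With the induced human DUX4 libraries left out, 10 genes lay more than 5 times above the lowest ratio, at 0.107% to 0.879%, which argues against that source alone for these 10. Transcription of the Zscan4 genes at levels that differ between the 5 other groups stayed open, since their share of counts gave p = 0.235 in a two-sided permutation test of 100000 permutations.

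Cell-cycle and cholesterol synthesis genes fell in the luciferase line. An effect of doxycycline or induction of one size in the 3 lines, with nothing added to it, was argued against for G2 and M-phase genes, where the largest median difference between lines was 1.99. For cholesterol synthesis genes the list tests did not decide it. There the largest was −0.640, between mouse Dux and human DUX4 (adjusted p = 0.000385, or 0.199 with an estimated correlation). The median differences from luciferase were −0.36 and 0.34 and did not pass. By gene, 17 of 25 had a higher and 7 a lower response with human DUX4 than with luciferase. With mouse Dux, 4 of 25 were higher and 14 lower than with luciferase. These counts argue against an effect of one size with nothing added, for the cholesterol synthesis genes that differed. An effect shared in part by the lines stayed open for this list. Exit from the cycle by muscle differentiation was argued against by sarcomere genes, which fell (median −0.682). With library size alone the G2 and M-phase median was −2.39, so the fall did not rest on the choice between TMM and library size. These 2 scalings differed by a median shift of only 0.0163 in this line, so they could not test scaling more widely. Both are relative, and a change in total RNA was not tested. G2 and M-phase genes also fell in the human DUX4 line, which carries no luciferase (median −2.16, difference from luciferase 0.08, adjusted p = 0.974). Single genes differed both ways, with 20 of 50 higher and 11 lower than with luciferase. An effect shared in part by these 2 lines stayed open. Effects of the luciferase protein, of the clone or of culture density stayed open too and were not tested, because each line is a single clone.

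One induced mouse Dux library, numbered 1, stood apart from the other 2, and the uninduced library of that number did so to a smaller degree. Across 9502 genes its deviation from them fell with transcript length (Spearman's rho −0.754), with medians of 0.28 in genes of at most 2120 nt and −0.41 in genes of at least 5569 nt, which is consistent with loss of signal from long transcripts in that library. The same trend was weaker in uninduced mouse Dux library 1 (−0.438), and rho spanned −0.303 to 0.213 in the other 2 lines. A trend with GC content was argued against by a rho of 0.148. A smaller share of responding cells stayed open. The 2-cell-stage genes had a median deviation of 0.106, but several of them are shorter than 2120 nt, where this library lay higher. They were not matched for length. Genes are not independent replicates, and no other biological explanation was tested. Without libraries numbered 1 the mouse Dux calls were 4700 higher and 5079 lower, while 3 list calls ended (double-homeobox genes with mouse Dux, adjusted p = 0.192, and, between mouse Dux and human DUX4, counterparts of human DUX4 targets, 0.119, and adipocyte and osteoblast markers, 0.0736).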

How the results depend on the processing

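Added after the data were seen were the subtraction of the luciferase response in list tests, limma-voom, both mouse Dux libraries numbered 1 left out, and a replicate block within the mouse Dux line; all other settings were planned. A result counts as reversed where its sign turned and it passed in either setting. With median-of-ratios factors, library size alone, no filter, DESeq2 and the replicate block, no count of called genes moved by more than 1.5 times. DESeq2 called 4741 higher and 4442 lower for mouse Dux, 4743 and 4268 for human DUX4, and 1673 and 2233 for luciferase. With only the groups compared in the fit, luciferase called 3032 higher, with 1974 of the 2004 kept. Against a minimum fold of 2, calls were 1335 higher and 665 lower for mouse Dux, 1068 and 980 for human DUX4, and 50 and 197 for luciferase. The 3852 genes called the same way became 250 with an absolute log2 fold change of at least 2. Of 80 list tests 42 passed, 15 with an estimated correlation and 72 with fry, which tests whether genes move one way without comparing other genes; stricter questions give fewer calls by construction, and the cause of the luciferase gain was not tested. With the luciferase response subtracted, the direction turned for G2 and M-phase genes with mouse Dux (1.99, adjusted p = 1.26e-24), cholesterol synthesis genes with human DUX4 (0.34, adjusted p = 0.0645) and, in the test though not the median, double-homeobox genes with mouse Dux (5.30, adjusted p = 0.780). Leaving out 1 library gave 4426 to 4800 higher and 4478 to 5114 lower for mouse Dux, 4409 to 4454 and 4273 to 4320 for human DUX4, 1543 to 1714 and 1809 to 1910 for luciferase, 3634 to 4408 called the same way, and 40 to 44 lists. Of the repeated tests of named genes without 1 library, 2466 gave the same outcome, called or not, 58 lost a call and 8 gained one. The replicate block gave 4622 and 4729, 4690 and 4527, and 1986 and 2204 genes, 3839 called the same way and 42 lists; it changed 8 list calls and that of Snai1 with luciferase (0.25, adjusted p = 0.0511) and no other. The block within the mouse Dux line, where libraries of one number were treated as pairs, ended 3 calls in 40 list tests. These were double-homeobox genes with mouse Dux (adjusted p = 0.194) and 2 calls between mouse Dux and human DUX4. The latter were counterparts of human DUX4 targets (0.0692) and adipocyte and osteoblast markers (0.0978). Of 159 tests of named genes, that block ended the call of Sycp3 with mouse Dux (−0.76, adjusted p = 0.0601). Without both mouse Dux libraries numbered 1 the same 3 list calls ended, as did 4 of named genes, and Myog gained one between mouse Dux and human DUX4 (−1.80, adjusted p = 0.00954). Same-numbered libraries correlated at −0.0470, 0.0394 and −0.0524 in the human DUX4 line and 0.0106, 0.0208 and −0.0145 in the luciferase line. Not every library in these lines matched its own number best. Depth limits genes with at most 3 counts, and 3 cultures per group limit what single libraries can show.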

Other observations

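The tests of neighbouring genes and of other splits of the libraries were planned before their results were seen, while the lengths set against fold changes were examined afterwards. After mouse Dux induction, strongly raised genes often lay next to each other. Of 847 strongly raised genes with a position, 2-cell-stage genes left out, 29.5% were next to another strongly raised gene, against a median of 12.3% and a highest value of 18.8% in 10000 random sets drawn from 13272 genes. Neighbouring genes may therefore be raised together, although tandem families outside the list add to this. Transcription running past the end of a raised gene into the next one stayed open. The next gene was strongly raised in 98 of 408 pairs (24.0%) where it lay downstream on the same strand. Otherwise it was so in 238 of 1281 pairs (18.6%), a ratio of 1.29 with p = 0.0187 in a two-sided Fisher's exact test. Pairs were taken from each raised member, so a raised pair on one strand counts in both groups. The groups are therefore not independent, and neither the ratio nor this p-value can decide the question.

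Each comparison of 3 libraries with 3 has 10 splits, too few for a share under 0.05. The real split called 9371 genes for mouse Dux, 9191 for human DUX4, 4228 for luciferase, 8883 for the uninduced mouse Dux line and 9923 for the uninduced human DUX4 line, and the highest other split called 0 in each by edgeR, as did those in the mouse Dux line that part as many pairs. In each of these 1 of 10 splits, the real one, reached the real count. At an unadjusted p under 0.05 the real splits gave 9656, 9465, 5381, 9278 and 10139 genes and the highest others 2350, 281, 425, 319 and 192. Other tools were not run on the splits. Lists were also counted in each split, adjusted over the 20 lists of one comparison. Every other split mixes induced and uninduced libraries unevenly, so part of the response stays in it. Lists passing there therefore do not show how many would pass without a response. For mouse Dux 13 passed against 10 in the highest other split, reached by 1 of 10 splits. For human DUX4 6 passed against 8, with 8 of 10 splits reaching 6, and for luciferase 9 against 11, with 7 of 10 reaching 9. Of 100 pairs of splits of the mouse Dux and human DUX4 libraries 1, the real one, gave 3852 genes called the same way. The highest other gave 0 in edgeR, which follows from the 0 genes called in every other split, so these pairs did not test chance for the overlap.

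Chi-square per degree of freedom between induced mouse Dux libraries was 35.7 for 1 and 2, 38.2 for 1 and 3, and 2.199 for 2 and 3. Between uninduced mouse Dux libraries it was 5.22 for 1 and 2, 5.29 for 1 and 3, and 1.26 for 2 and 3, so the uninduced library numbered 1 stood apart as well, by less. Across 9502 genes the log2 fold change and transcript length had a Spearman's rho of 0.0129 for mouse Dux (0.116 without libraries numbered 1), 0.0893 for human DUX4 and 0.213 for luciferase.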
